A study of Mus musculus with 8 samples.

How the data were processed

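Gene expression was measured in total RNA from mouse on 8 Affymetrix Mouse Genome 430 2.0 arrays, 4 labelled Ctrl and 4 labelled Exp. Groups and the numbers 1 to 4 were taken from the sample titles. The labels state no treatment, genotype or age, and do not explain the abbreviation that stands before the numbers.

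The deposited values are probe set intensity values on a linear scale, with 1 value per probe set and array. How the authors computed them is not given in the sources used here. In the deposited table the mean without the lowest and highest 2% of probe sets was 2500 in every array, a property that global scaling of each array gives. No value was missing or at or below 0. A scaling of this kind removes any difference in total signal between arrays, so that fold changes are relative to the bulk of the probe sets. The values carry no detection call or background here, and low signals are therefore compressed by the pseudocount in a way that understates their fold changes. All columns of the table were mapped to samples.

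Signals were taken as log2(signal + 16). The design, written before the data were examined, called for quantile normalization where the arrays' medians of log2 values differed by over 0.2. The largest difference between medians was 0.203, just over this limit, and quantile normalization was applied. The wording of that rule left open whether it covered linear values as well as values deposited as log2; it was read as covering both, and the unnormalised values serve as an alternative. The 64 control probe sets were left out, as were probe sets whose mean lay under the 40th percentile (a signal of about 333), which left 27022. Exp was compared with Ctrl by limma 3.58.1 in R 4.3.3 with lmFit and eBayes, two-sided, with Benjamini-Hochberg adjustment over all tested probe sets and a 5% false discovery rate. With this scale a fold change is that of signal + 16.

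Gene names came from the platform's annotation table, updated by Entrez identifier through the RefSeq gene table of assembly GRCm38.p6. Of 45037 probe sets other than controls, 34945 carried 1 gene name, 932 several and 9160 none, and 34741 of those with 1 name matched the RefSeq table by identifier. No gene was named from a probe set with several names. The files name no genome build, so the RefSeq table served for names, for which genes neighbour each other and for which genes share a chromosome, and none of its coordinates are given. Different probe sets of a gene were kept apart, and where 1 was needed the one with the highest mean over all arrays was used, for 12763 genes.

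The 35 gene lists held 943 genes, of which 865 were on the array and 661 were tested. Lists with at least 5 measured genes were tested with camera at its preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the 33 lists. Camera with an estimated correlation and fry, which tests whether a list's genes move one way without comparison to other genes, were run beside it. As a further test, added later, the mean of each list per array was compared by an exact permutation test, two-sided, over all 70 orders of the arrays.

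The genes to be named were fixed by rule before the data were examined. They were the 10 largest changes per direction past the threshold with groups that did not overlap, or, where fewer than 5 passed, the 5 genes with the smallest p in that direction; up to 4 members of each list with the smallest p; and 14 genes named in advance. The number of members per list, 2, or 4 for a called list, was set within that limit after the data had been seen. Of the genes named in advance, Calca and Gapdh were not analysed here, and some others are not reported here. Genes and probe sets named outside the rule are said to be so where they appear.

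The pipeline was tested on simulated data before use. With 200 of 27022 probe sets changed, 14% were recovered at a log2 change of 0.5, 64% at 1, 92% at 1.5 and 100% at 2, with 2 false calls. When only 1 probe set was changed, it was called in 0 of 20 runs at a log2 change of 1, in 17 at 2 and in 19 at 2.5. A list of 34 genes shifted by 0.3 was called, and 0 of 32 other lists were. The simulated genes varied independently of each other, so this gives no rate of false calls for lists whose genes correlate.

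Alternatives planned in advance were other pseudocounts (1 and 64), no filter, a filter at the 60th percentile, no quantile normalization, centring on medians, the replicate number as a block, trend and robust options, array weights, an estimated correlation, fry, the mean of a gene's probe sets, and leaving out each array. Added after the data were seen were a pseudocount of 256, the Eif2s3y signal as a covariate for the animals' sex, and leaving out both Exp 2 and Exp 3. Figures were drawn with matplotlib 3.10.9.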

Results

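Total RNA of mouse origin was hybridised to 8 Affymetrix Mouse Genome 430 2.0 arrays, which measure transcripts with sets of short oligonucleotide probes. The labels place 4 arrays in a control group, called Ctrl, and 4 in a group called Exp, and they do not state what the Exp animals or samples underwent. The tissue is given as trigeminal ganglion, the sensory ganglion of the face, in one label field and as brain and adrenal medulla in another. Within each group the arrays carry the numbers 1 to 4, and nothing states that each came from a separate animal, so each p-value measures only the spread between these arrays, which may in part be technical. Signals of Xist and of the Y-linked gene Uty differed within both groups as between sexes, so each group held more than 1 animal. The deposited values are linear signals, and every array had a trimmed mean signal of 2500, with a median between 478 and 553 across all 45101 probe sets. The number of arrays, 4 per group, limits the precision of every comparison. The comparison that the labels imply, and the question addressed here, is which transcripts differed between Exp and Ctrl.

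The Exp and Ctrl arrays were close to each other in the transcripts of sensory neurons, and a single probe set of the 27022 tested passed the 5% false discovery rate. That probe set reads 1300017J02Rik, a gene next to Trf (transferrin) in the mouse assembly GRCm38.p6. Its signal rose by 2.43 log2 units in Exp (SE 0.21, 95% confidence interval 1.96 to 2.91, a 5.39-fold difference on the log2(signal + 16) scale; limma, adjusted p = 0.0310), from 8.30 ± 0.13 in Ctrl to 10.7 ± 0.45 in Exp (SD, n = 4 each), and all 4 Exp arrays lay above all 4 Ctrl arrays. The nearest tested genes on either side of it, Srprb and Topbp1, differed by -0.07 (SE 0.11) and -0.05 (SE 0.11). Trf lies between Srprb and 1300017J02Rik and had no tested probe set that names it alone. Probe sets with several gene names were not assigned to a gene, so the change of Trf is not known here. The call ended in 7 of the 8 fits without 1 array, and it held only without Exp 2, although the log2 fold change stayed between 2.32 and 2.64. It ended also without a filter on low signals (adjusted p = 0.0966), with the replicate number as a block (2.43, SE 0.16, adjusted p = 0.128) and with the Eif2s3y signal as a covariate for sex, added after the data were seen (2.39, SE 0.21, adjusted p = 0.0795), models that leave fewer degrees of freedom, and a filter at the 60th percentile removed the probe set. In a test chosen after the results were seen, the chromosome of 1300017J02Rik held 16 of the 100 genes with the smallest p against 5.77 expected, an excess that passed in 4 of 13 alternatives and came to 9 genes without Ctrl 3 or Exp 4 and 11 without a filter.

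No other probe set passed, and none was called lower in Exp. With each gene represented by its brightest probe set only, the genes with the next smallest p among higher signals were Obi1, a ubiquitin ligase of replication origins, with a log2 fold change of 1.66 (SE 0.24, adjusted p = 0.445), Cdh5, the cadherin of endothelial junctions, with 0.63 (SE 0.10, adjusted p = 0.445), Spata9 with 0.81 (SE 0.14) and the homeobox gene Dlx4 with 0.52 (SE 0.09). Among lower signals, under the same limit, they were Zfp235, a zinc finger gene, with -0.94 (SE 0.14), Alg12, a mannosyltransferase of protein glycosylation, with -1.35 (SE 0.21), Maob, a monoamine oxidase, with -0.60 (SE 0.10), G6pc3, a glucose-6-phosphatase subunit, with -1.29 (SE 0.24), and Fbxo10 with -0.57 (SE 0.11). For each of these 9 genes the 4 Exp values lay on one side of the 4 Ctrl values, but none passed the threshold in limma. The other tested probe set of Zfp235 differed by 0.04 (SE 0.14, limma unadjusted p = 0.777).

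**Figure D1:**
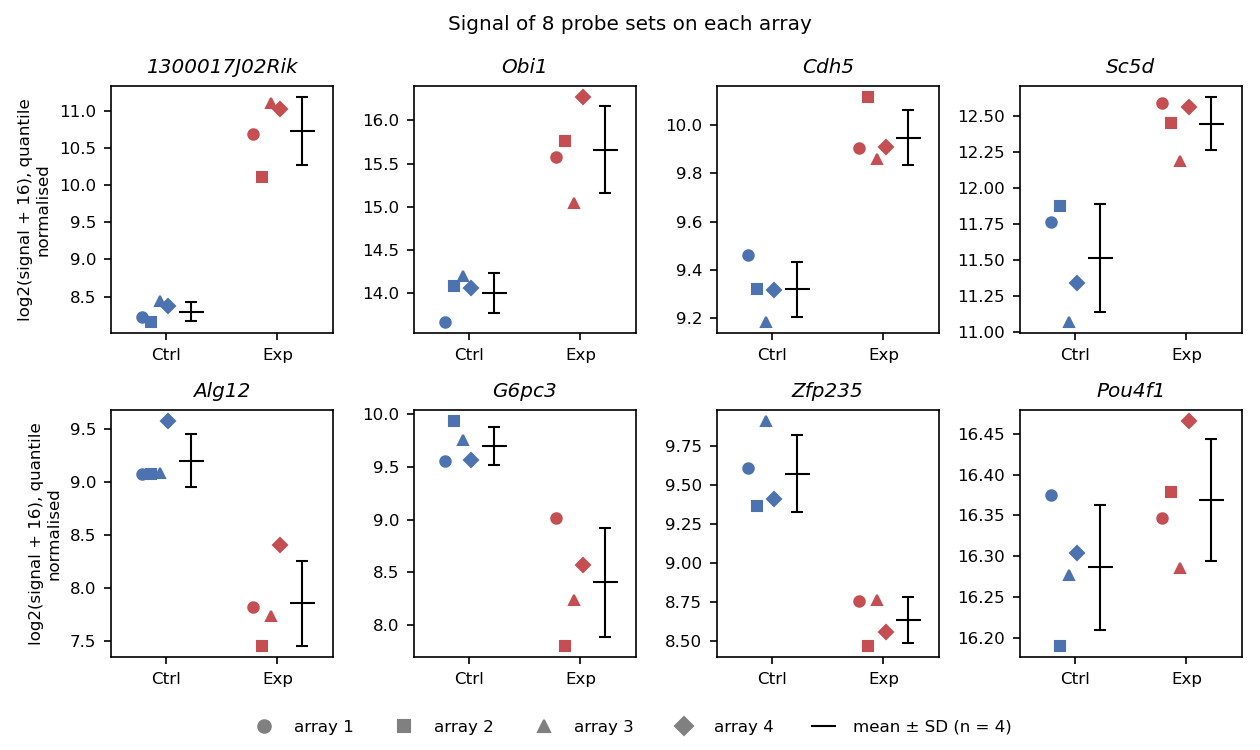
Quantile-normalised log2(signal + 16) of 8 probe sets, 1 per panel, in the Ctrl and Exp groups; each point is 1 array and the bars show the mean and SD of 4 arrays. 1300017J02Rik lay near 8.30 in Ctrl and 10.7 in Exp, while Pou4f1 overlapped between the groups; the vertical scales differ between panels and do not start at 0.

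Across all probe sets, 1266 had an unadjusted p below 0.05 (590 higher and 676 lower in Exp), against 1351 expected by chance, and 39 had p below 0.001, against 27.0 expected. The groups did not overlap in 632 probe sets, or 2.34% of those tested, where chance gives 2.86%. The mean correlation between arrays across probe sets was 0.974 within groups and 0.974 between groups. The median standard error of a log2 fold change was 0.154, and for 93.5% of the probe sets the 95% confidence interval excluded a doubling in either direction.

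Genes that mark the identity of sensory neurons did not separate the groups. Pou4f1 and Isl1, transcription factors of sensory neuron differentiation, differed by 0.08 (SE 0.09) and 0.00 (SE 0.09) log2 units. Ntrk2 and Ntrk3, the receptors for BDNF and neurotrophin-3, differed by 0.04 (SE 0.17) and -0.23 (SE 0.16), the neuropeptide precursor Tac1 by 0.08 (SE 0.23), the neurofilament gene Nefh by -0.02 (SE 0.21) and the intermediate filament gene Prph by 0.00 (SE 0.09). Th, the enzyme that limits catecholamine synthesis, differed by -0.07 (SE 0.17), and Actb, cytoskeletal actin, by 0.02 (SE 0.09), each in the gene's brightest probe set. Of their other tested probe sets, one of Actb differed by 0.67 (SE 0.24, unadjusted p = 0.0209) and one of Ntrk2 by 0.37 (SE 0.16, unadjusted p = 0.0398). None of these passed limma's test.

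Of the 33 gene lists with enough measured members, 3 were called by camera, a test that sets a list against all other genes. In each called list the genes' mean correlation within groups exceeded camera's preset of 0.01. It was 0.498 for muscle, 0.189 for cholesterol and 0.185 for Schwann cell genes, so the preset p-values overstate the evidence. Skeletal muscle markers were higher in Exp, with 15 of 16 genes higher and a median log2 fold change of 0.58 (adjusted p = 2.16e-06). With an estimated correlation the adjusted p was 0.706 for this list, and the exact two-sided permutation test of the list means per array gave p = 0.286 (n = 4 per group), with a smallest possible p of 0.0286. Myh8, a myosin of developing muscle, differed by 1.40 (SE 0.60), Actn2, an actinin of the sarcomere, by 1.32 (SE 0.58), Actn3 by 0.26 (SE 0.13) and Myod1, the transcription factor of the muscle lineage, by 0.39 (SE 0.15). None passed when adjusted over all probe sets or adjusted over the list alone. The list mean was 1.53 log2 units above the 8-array mean in Exp 3, 0.47 above it in Exp 2, -0.06 from it in Exp 1 and -0.67 from it in Exp 4, while the Ctrl arrays lay between -0.42 and -0.22. Without Exp 3 the median was 0.19 over the 12 genes that then passed the filter (adjusted p = 0.0301), and without Exp 4 it was 1.05 over 16 genes (adjusted p = 9.00e-12). Epithelial and keratinocyte markers had the same order of Exp arrays, with means of 0.45 in Exp 3, 0.27 in Exp 2, -0.04 in Exp 1 and -0.34 in Exp 4, against -0.14 to 0.01 in Ctrl.

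Cholesterol synthesis genes were higher in Exp as a list, with 16 of 20 genes higher, a median of 0.07 and an adjusted p of 0.00513 by camera. With an estimated correlation the adjusted p was 0.706, and the exact permutation test of the list means gave p = 0.0571. The largest difference was that of Sc5d, the sterol C5-desaturase, at 0.93 (SE 0.19), which passed when adjusted over the list alone (adjusted p = 0.0163) but not over all probe sets (adjusted p = 0.630) and lies on the same chromosome as 1300017J02Rik. Srebf2, the transcription factor of sterol synthesis, differed by 0.29 (SE 0.14), Nsdhl, a sterol dehydrogenase, by 0.16 (SE 0.12) and Pmvk, a kinase of the mevalonate pathway, by 0.12 (SE 0.09). The call ended without Ctrl 1 (adjusted p = 0.0517), Ctrl 2 (0.0721), Exp 3 (0.0965) or Exp 4 (0.0511), and over the fits without 1 array the median ran from 0.04 (without Ctrl 2) to 0.14 (without Exp 2, adjusted p = 1.03e-04).

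Schwann cell and myelin markers were lower in Exp, with 14 of 18 genes lower, a median of -0.16 and an adjusted p of 0.00545 by camera. With an estimated correlation the adjusted p was 0.706, and the exact permutation test gave p = 0.143. Plekhb1 differed by -0.53 (SE 0.16), Sox10, the transcription factor of the glial lineage, by -0.33 (SE 0.14), Cdh19, a cadherin of the Schwann lineage, by -0.24 (SE 0.11) and Mbp, myelin basic protein, by -0.34 (SE 0.19). Egr2, the transcription factor of myelination, differed by -2.66 with an SE of 0.97, and its signal varied within both groups, with an SD of 1.81 in Ctrl and 1.51 in Exp. None passed when adjusted over the list alone. The call ended without Ctrl 1 (adjusted p = 0.204), Exp 1 (0.134) or Exp 3 (0.189), and without a filter on low signals (0.0717), whereas without Exp 2 the median was -0.27 over 17 genes (adjusted p = 1.77e-05). The list mean was -0.40 in Exp 1, -0.30 in Exp 3 and -0.02 in Exp 4, but 0.18 in Exp 2, above 3 of the 4 Ctrl arrays (0.00 to 0.30). Satellite glia markers were likewise highest in Exp 2 among the Exp arrays, at 0.11, and lowest in Exp 3, at -0.18. The 3'/5' signal ratio of the actin control was 0.19 log2 units higher in Exp (4.36 ± 0.07 against 4.55 ± 0.12, SD, n = 4 each, exact permutation p = 0.0571), whereas that of Gapdh differed by -0.05 (exact permutation p = 0.743). On the linear scale the actin ratio ran from 19.8 to 25.5 and the Gapdh ratio from 14.6 to 20.7 over all arrays. The 3' ends of these controls thus gave far more signal than the 5' ends in both groups. Whether this bears on genes whose probe sets disagree was not tested. The signal of 18S ribosomal RNA differed by -0.29 (exact permutation p = 0.114).

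**Figure D2:**
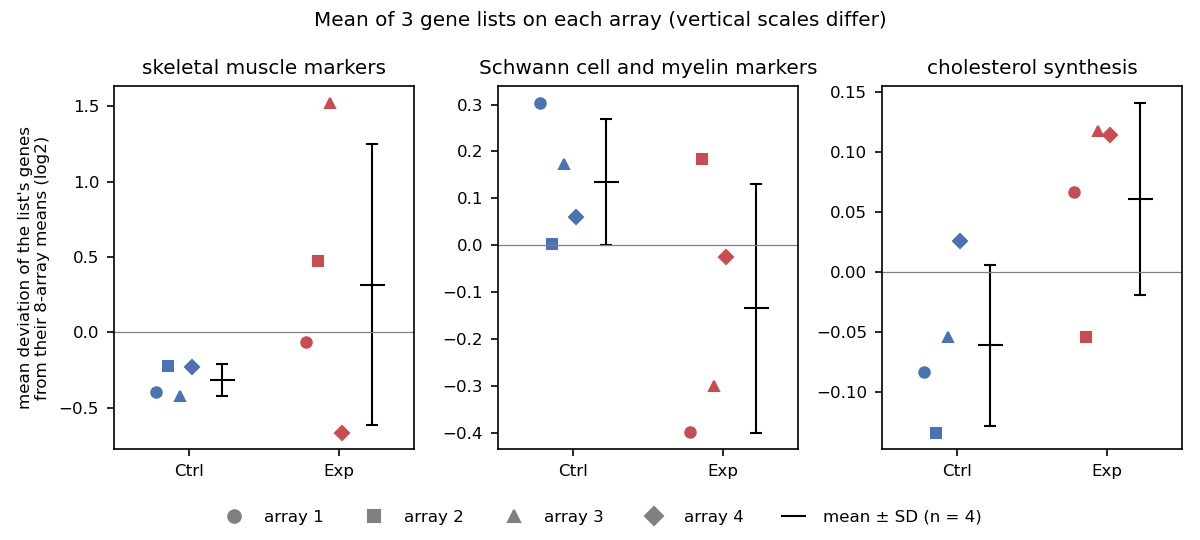
Mean deviation of the genes of 3 lists from their 8-array means, in log2 units, in the Ctrl and Exp groups; each point is 1 array and the bars show the mean and SD of 4 arrays. The muscle list reached 1.53 in Exp 3 and -0.67 in Exp 4, on either side of the Ctrl arrays; the vertical scales differ between panels.

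The other 30 lists were not called by camera, and no member of any list passed when adjusted over all probe sets. Among the neuronal lists, sensory neuron transcription factors had 11 of 25 genes higher (adjusted p = 0.8285), with Klf7 at 0.29 (SE 0.11) and Lmo2 at -0.37 (SE 0.16). Neurogenic factors and the Notch pathway had 10 of 25 higher (0.743), nociceptor and thermoreceptor genes 16 of 25 (0.743) and mechanoreceptor and large fibre genes 12 of 25 (0.948). Neurotrophic factor signalling had 9 of 17 higher (0.581), synaptic vesicle and release genes 12 of 27 (0.581), voltage-gated channels 12 of 25 (0.948) and neurotransmitter receptors 10 of 25 (0.769). Axon guidance and growth genes had 20 of 35 higher (0.8285). In that list the netrin receptor Dcc differed by -0.74 (SE 0.19) and the ephrin receptor Ephb1, on the chromosome of 1300017J02Rik, by -0.60 (SE 0.19), and neither passed. Nerve injury response genes had 8 of 22 higher (0.948), with Npy, a peptide of injured and sympathetic neurons, at -0.70 (SE 0.23). Hox and other segmental homeobox genes had 5 of 14 higher (0.799).

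General cell programmes were not called. Cell cycle genes had 15 of 34 higher (adjusted p = 0.948), apoptosis genes 5 of 23 (0.581), immediate early genes 11 of 25 (0.928) and heat shock and unfolded protein response genes 14 of 29 (0.743). Oxidative phosphorylation had 9 of 35 higher (0.743), glycolysis and hypoxia response 10 of 26 (0.948), interferon response 4 of 15 (0.581) and extracellular matrix 18 of 35 (0.581). In the heat shock list the small heat shock protein gene Cryab, on the chromosome of 1300017J02Rik, differed by 0.46 (SE 0.16), and in the interferon list Oas1a, a sensor of double-stranded RNA, by -0.44 (SE 0.16).

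Markers of other cell types were not called either, beyond those above. Satellite glia markers had 16 of 20 genes lower (adjusted p = 0.0695) and were called in 4 of 21 alternatives, with the replicate block (0.0438) and without Ctrl 3 (0.0416), Ctrl 4 (0.0497) or Exp 2 (0.00273). Of the others, central neuron markers had 11 of 13 lower (0.581), chromaffin and sympathetic markers 14 of 19 (0.135) and pituitary markers 5 of 6 (0.109). Astrocyte and oligodendrocyte markers had 5 of 12 lower (0.900), adrenal cortex markers 3 of 7 (0.787), erythroid markers 7 of 12 (0.787), cartilage and bone markers 5 of 10 (0.936) and macrophage and leukocyte markers 10 of 18 (0.787). Endothelial and mural markers had 17 of 22 lower (0.951), although Cdh5 was higher and passed when adjusted over the list alone (adjusted p = 0.00435, limma). Epithelial and keratinocyte markers had 10 of 14 higher (0.293), and Grhl2, a transcription factor of epithelia, at 0.50 (SE 0.12), passed when adjusted over the list alone (adjusted p = 0.0369, limma) but not over all probe sets (0.937). In the endothelial and the epithelial list, as in the cholesterol list, 1 gene passed in this way, and 0 passed in each of the other 30 lists. This adjustment takes no account of the number of lists, so some such passes would be expected by chance alone. With fewer than 5 measured genes, 2 lists were not tested. These were the retina and lens markers, with 3 measured genes, and the Y-linked and X-inactivation genes, with 4.

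**Figure D3:**
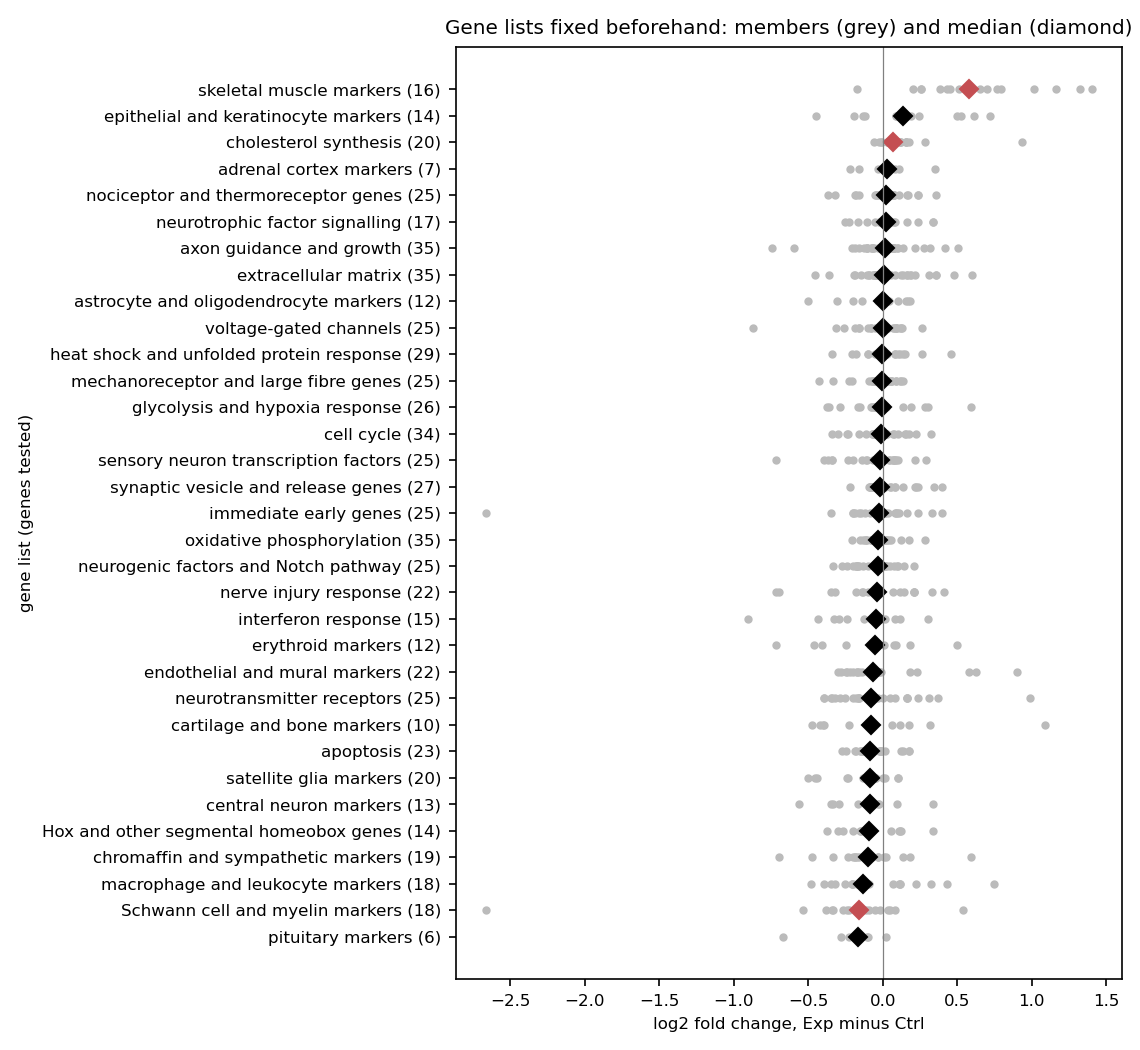
Log2 fold change (Exp minus Ctrl) of the tested members of the 33 gene lists (grey points) and the median of each list (diamonds, red where camera with its preset correlation called the list). The medians lay between -0.17 and 0.14 except that of the skeletal muscle markers, at 0.58; numbers in parentheses are genes tested.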

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

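The tests of the muscle list below were chosen only after its result was seen. In each group of 4 arrays, the named genes, the lists and the control ratios were examined for a value whose gap to its nearest neighbour exceeded Dixon's critical share of the group's range. This met 11 of 252 groups, where chance gives about 12.6, so the number of such values is no greater than chance.

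Among genes, Ctrl 4 lay apart for Alg12 at 9.57 (the others 9.07 to 9.08) and for Maob at 10.1 (10.0979, the others 10.13 to 10.14). Ctrl 3 lay apart for the Y-linked gene Uty at 7.77, and Ctrl 1 for Ntrk2 at 13.1. In the Exp group, Exp 1 lay apart for Cacnb1, a calcium channel subunit, at 7.22 and for Isl1 at 15.99, Exp 3 for Bcl2l1, an inhibitor of apoptosis, at 11.9, and Exp 4 for Aurka, a mitotic kinase, at 9.20. Of the lists, Exp 1 lay apart in axon guidance and growth, at 0.0691, and Ctrl 2 in nerve injury response, at 0.104. For the 3'/5' ratio of the Gapdh control, Exp 1 lay apart at 4.08 (log2).

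The skeletal muscle list was called as higher in Exp, yet 15 of its 16 genes had their highest signal in Exp 3. For Acta1, Actn2, Myl1 and Chrna1 the mean of the other 7 arrays lay under the filter's cut of 8.45 (log2). These genes passed the filter only through Exp 3, so their high signal there is in part a result of the filter. A change shared by the 4 Exp arrays goes against the value of Exp 4, -0.67, which lay below the lowest Ctrl array at -0.42. Muscle tissue carried along in some arrays cannot be told apart from a difference that the undisclosed Exp condition made in some animals, which was not tested. In Exp 3 muscle genes stood above the mean of the other 7 arrays by 3.51 (Myh3), 2.79 (Mylpf) and 2.35 (Acta1) log2 units, and the median of the 16 was 2.00. Carried-along tissue was predicted to raise every gene of the list clearly in Exp 3, and this was not met. Eno3 (0.44), Casq1 (0.39), Actn3 (0.37) and Myod1 (0.34) rose little, and Ckm, muscle creatine kinase, differed by -0.23. These smaller values do not decide between the accounts. Of the 16 genes, 0 belong to another list, and the epithelial list was also highest in Exp 3 (0.45) and lowest in Exp 4 (-0.34). The mean correlation of 0.498 between the list's genes, taken over deviations from the group means, was first read as support for carried-along tissue and is not counted, since genes that are highest in the same array correlate whatever the cause.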

How the results depend on the processing

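The settings added after the data were seen are the highest pseudocount, the Eif2s3y covariate and leaving out both Exp 2 and Exp 3. The count of probe sets past the threshold, 1, fell to 0 without a filter, where more probe sets were tested, with the filter at the 60th percentile, which removed 1300017J02Rik itself, with the replicate number as a block, and with the Eif2s3y covariate. Without 1 array it ranged from 0 to 1. The adjusted p of 1300017J02Rik was 0.0966 without a filter and 0.0795 with the covariate, and over the fits without 1 array it ran from 0.00208 (without Exp 2) to 0.232 (without Ctrl 1), while its log2 fold change was between 1.81 and 2.64 in all fits. The design, fixed beforehand, used the numbers as a block only in an alternative and not as pairs. Same-numbered arrays of the groups did not deviate together (r = 0.02, 0.05, -0.07 and -0.12 across probe sets). Differently numbered ones ran from -0.17 to 0.20. Deviations from group means make such correlations average near 0, so this check says little about pairing. The replicate block gave 0 probe sets, with an adjusted p of 0.128 for 1300017J02Rik, and 4 lists, the fourth being satellite glia markers.

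The count of called lists, 3, was 5 with the Eif2s3y covariate, 0 with an estimated correlation and 0 with fry in place of camera, and ranged from 1 to 4 without 1 array. With an estimated correlation only that setting of camera was changed, so the loss of the calls follows from replacing the preset of 0.01. Fry asks another question, and the cause of the other changes was not tested. Each of the 3 called lists kept its direction in all 21 alternatives and was called in 18 (skeletal muscle markers), 15 (cholesterol synthesis) and 15 (Schwann cell and myelin markers). Of the 30 lists not called, satellite glia markers were called in 4 alternatives, epithelial and keratinocyte markers in 2, and synaptic vesicle and release genes, extracellular matrix, chromaffin and sympathetic, pituitary, and macrophage and leukocyte markers in 1 each. Without both Exp 2 and Exp 3 the muscle list was not called (adjusted p = 0.674, median 0.03). Of 1761 values of the 90 named genes under alternatives, 1734 kept their direction, 27 turned it, all of them for genes that were not called, and 0 were newly called. Signal over background could not be judged, since no detection call was used here.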

Other observations

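The tests in this part were chosen after the results were seen, except the counts of probe sets and lists over other splits of the arrays, which were planned. The genes and probe sets named here outside the naming rule were chosen after their values were seen. A probe set that is assigned to several genes, and is therefore not named, had a difference of 2.53 log2 units in Exp (SE 0.49, limma adjusted p = 0.589), and its 4 Exp values lay above its 4 Ctrl values. Rhobtb3, the direct neighbour of Spata9, was the only gene of 5758 with several probe sets that had p below 0.001 in both directions: one differed by 1.12 (SE 0.17) and another by -1.25 (SE 0.23), while the brightest differed by 0.10 (SE 0.09). Phka1, a subunit of phosphorylase kinase, had a probe set at 1.13 (SE 0.14, adjusted p = 0.378) and its other probe sets at 0.18 and 0.15. Obi1 is the direct neighbour of Pou4f1, which itself differed by 0.08.

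Other genes with large differences that did not pass in limma were the ubiquitin-activating enzyme Uba6 at -1.52 (SE 0.24), Sae1, of the SUMO-activating enzyme, at -1.34 (SE 0.22), and Pax3, a transcription factor of the neural crest, at -0.85 (SE 0.14), each with an adjusted p of 0.445 and each from a probe set that is not the gene's brightest. The brightest probe sets of Uba6, Sae1 and Pax3 differed by -0.01, -0.04 and -0.15. Xist, the RNA of the inactive X chromosome, was near 15 on the log2 scale (15.1, 15.6 and 15.3) in Ctrl 3, Exp 1 and Exp 4, and between 9.47 and 10.8 in the other 5 arrays. The Y-linked gene Uty was low (7.77, 7.38 and 7.98) in the same 3 arrays, so the sexes were mixed within both groups.

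Of the 35 splits of the 8 arrays into 4 and 4, 4 gave at least the 1 probe set of the real split (the highest of the other splits gave 3), and 21 gave at least its 3 lists (highest other 11), so chance cannot be excluded for either count. The muscle list was called in 20 of the splits. As many probe sets with an unadjusted p below 0.05 as the real 1266 came from 17 splits. The highest other split, Ctrl 1, Exp 1, Exp 2 and Exp 4 against the rest, gave 3523, and its cause was not tested. These arrays had the highest median deposited signals, 553, 539, 532 and 548, against 478 to 511 in the rest. All Exp arrays but Exp 3 are among them, and of Ctrl only Ctrl 1. Whatever sets these arrays apart is therefore partly confounded with the groups.

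The higher signal of 1300017J02Rik did not rest on a single array, since its log2 fold change was at least 2.32 in every fit without 1 array. With groups that did not overlap, leaving out 1 array could hardly have given another outcome. Its call, by contrast, held in only 1 of the 8 fits. Stretches of the genome that differ between the animals of the groups were considered as a candidate explanation, with the prediction that neighbouring genes would appear together among those with the smallest p. The test did not support it and cannot exclude it: the 100 genes with the smallest p held 1 pair of neighbours (at most 3 tested genes apart), where the median of 10000 random sets was 2 and their 95th percentile 5 (permutation p = 0.912). Probe sets assigned to several genes, and genes without a tested probe set of their own, such as Trf, did not enter this test. Each gene entered by its brightest probe set only, so changes in other probe sets of neighbours were not counted. Such probe sets of Rhobtb3, beside Spata9, differed by 1.12 and -1.25. A probe set of Sorl1, the direct neighbour of Sc5d, differed by 1.28 (SE 0.34, limma unadjusted p = 0.00487), while the brightest of Sorl1 differed by -0.06 (SE 0.14). The bound set for excluding this explanation, no more pairs than the random median, was met but was too lenient, since the 95% Poisson limit of a count of 1 reaches 5.57, and the explanation stays open. A sequence difference under the probes of 1300017J02Rik was not tested, as no probe sequences were used here, and a biological effect of the Exp condition stays open.

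After that test had shown no excess of pairs, the chromosomes of the genes with the smallest p were compared, with 6 list sizes tried. The chromosome that carries 1300017J02Rik held 4 of the first 25 genes (1.44 expected), 6 of 50 (2.89), 16 of 100 (5.77), 32 of 200 (11.5), 44 of 400 (23.1) and 78 of 800 (46.2); hypergeometric p-values adjusted over the 19 autosomes were 1, 0.633, 0.00347, 2.55e-06, 5.28e-04 and 5.29e-05. At 200, 400 and 800 genes another autosome passed as well (smallest adjusted p 0.0383, 0.00112 and 0.00334). The excess among 100 genes passed in 4 of 13 alternatives, and in 1 of the 8 fits without 1 array (9 to 14 genes); among 200 genes it passed in 10 of 13, and it did not pass without a filter on low signals (17 genes, adjusted p = 0.489).

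For 100 genes, 5 of the 35 splits gave some chromosome as small a p, so chance cannot be excluded in that form; the other 4 owed it to the Y chromosome, that is to sex. For 200 genes, with all chromosomes counted, 1 of the 35 splits did, the real one, with 32 genes on this chromosome against at most 20 in the others, although this size was 1 of the 6 tried. Counting autosomes only among 100 genes, a choice made once this had been seen, 1 of the 35 splits did, the real one, with 16 genes on this chromosome against at most 12 in the others. A different number of copies of the chromosome goes against the median log2 fold change of its 735 genes, which differed from that of the other genes by -0.00539, where 1 more copy would give 0.585. Inherited differences along part of the chromosome, such as a strain's sequence around an altered locus, could give changes in both directions (20 lower and 12 higher among the 32), but cannot be told apart from other accounts: 4 of the 32 lay in the first 25% of its tested genes, where 7.97 would be expected (exact hypergeometric p = 0.0672), and that test was picked with the positions already in view. The excess is a hypothesis to be followed up with genotypes, not a finding.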
